A study of Mus musculus with 2 samples.

How the data were processed

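Single-cell RNA sequencing data from mouse brain at embryonic stage E12.5 were analysed, with 1 library per genotype. Per the labels, the tissue was dissociated with enzymes, cells were sorted with CD31 microbeads, and single cells were captured with barcoded beads in microwells on the NovelCyto system, which tags the 3′ end of each transcript with a unique molecular identifier (UMI). The deposited values were counts, whole numbers of UMIs per gene and cell barcode, with no normalization. The submitters' processing notes name fastp 0.24.0, STARsolo 2.7.11b and the mouse build mm10, without their order or settings. The annotation version, the treatment of reads that align to several genes and the filter on barcodes are not given in the sources used here. Every barcode held at least 500 UMIs, and the profile of free RNA was not estimated from empty wells.

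Groups were taken from the genotype labels. Each library held 31253 genes, and 48 symbols shared by more than 1 gene were kept apart by their identifiers. Cells with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. Doublets were called in each library with Scrublet as run by scanpy 1.11.5, with an expected share of 8%, and were removed. Both libraries were then normalized to 10000 UMIs per cell and log-transformed, and clustered together without batch correction, on 2000 variable genes, 30 principal components and 20 nearest neighbours, with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Endothelial-like cells were clustered again at resolution 0.6. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.

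Clusters were named from marker lists of 15 cell classes, and endothelial subclusters from marker lists of 6 subtypes. A name needed at least 3 markers at 50 or more CPM (summed counts scaled to the total of the cells summed) and 2-fold or more above the other cells, with a pseudocount of 5 CPM. A cluster whose 10 leading genes held more markers of another class than of its own stayed unnamed, as did a cluster with at least 3 cartilage genes among them. A cluster that also held at least 50% of the markers of an unrelated class was called mixed.

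UMI counts were summed over the cells of a class in each library and expressed as CPM. A level has an exact Poisson interval, a share of cells an exact binomial interval (Clopper-Pearson), and a ratio of levels an exact conditional binomial interval, all at 95%. These intervals cover counting error only. With 1 library per group no test between genotypes was possible, so no p-value or standard error is given and the differences have no replicate check. Differences are described by size: a gene counted as higher or lower by size when its ratio was at least 1.5 in that direction and its counting interval excluded 1. Log2 ratios are the Foxq1iECKO library over the Foxq1flox/flox library throughout.

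Genes were named by a fixed rule. In pooled endothelial-like cells, genes at 20 or more CPM in at least 1 library were ranked by the limit of the interval of the log2 ratio nearest to 0, and the 12 highest and 12 lowest were named, except 1 gene that is not reported here. Foxq1 was always named. Mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes, predicted genes without a symbol, and genes over 5 times higher in another class of 100 or more cells in the same library were left out of this ranking. In other classes of 200 or more cells in both libraries, the 5 highest and 5 lowest genes by the same ranking were available. For 29 gene lists, members at 10 or more CPM in at least 1 library counted as measured, and up to 4 members were named, the extreme ones by size first and then the most abundant. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Its interval came from 1000 Poisson draws. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. The 3′ tags were not used to place the deleted part of Foxq1, which the labels do not describe.

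The size rule was tested on simulated counts for 6116 genes of the endothelial-like comparison. It found 56.7% of 67 genes simulated at 1.5-fold, 97.0% of 67 at 2-fold, 98.5% of 66 at 4-fold and 0% of 5858 unchanged genes. The intervals held the simulated ratio for 97.0%, 97.0%, 95.5% and 95.1% of these genes. Both libraries were Poisson draws from a shared profile, the model that the intervals assume. These rates therefore cover counting error only, not differences between embryos, collections or mixes of cells.

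Cell filters, marker and gene lists, the naming of genes, the size rule and most alternatives were fixed before the data were examined. These covered scaling by the median of ratios (DESeq2 1.42.0) and by TMM (edgeR 4.0.16), other cell filters, doublets kept, other resolutions, a marker gate per cell, equal weights for cells or for subclusters, cycling cells left out, other expression minimums and other thinning depths. With equal weights for subclusters, each subcluster took its mean share over both libraries as its weight in both. Chosen after the data had been seen were the numeric naming details, the rules for mixed and cartilage clusters, and the alternatives that added the mixed cluster, left out the endothelial-like cluster of low UMI count or kept only barrier subclusters. Also chosen then were the clusterings without genes 1.5-fold apart, the normal intervals on the log scale for weighted levels, and a narrower definition of a turned sign, which required the interval of the original value to exclude 0 or, for a list median, a percentile among the outer 2.5% on either side. Spliced and unspliced transcripts and sequence variants were not analysed here.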

Results

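Cells sorted with CD31 microbeads from embryonic mouse brain were profiled at embryonic stage E12.5. There was 1 library from Foxq1flox/flox brains and 1 from Foxq1iECKO brains. FOXQ1 is a forkhead transcription factor, and the comparison addresses its part in the growth of brain vessels and in the forming of the blood-brain barrier. The Foxq1flox/flox library held 76580165 UMIs over 15837 barcodes and the Foxq1iECKO library 72445925 UMIs over 15108 barcodes. The median cell had 3836 and 3660 UMIs and 2008 and 1914 genes, and mitochondrial transcripts made up a median of 6.38% and 6.48%. After filtering, 13933 and 13108 cells remained, and after removal of 557 and 551 predicted doublets (4.0% and 4.20%), 13376 and 12557 cells were used. How many embryos entered each library is not given in the sources used here. Values are given for the Foxq1flox/flox library first, and brackets hold 95% counting intervals.

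Foxq1, the targeted gene (ENSMUSG00000038415), was lower in the endothelial-like cells of the Foxq1iECKO library. Its level was 434 CPM [424, 444] in 2305 endothelial-like cells of the Foxq1flox/flox library and 143 CPM [135, 150] in 1539 of the Foxq1iECKO library, from 7286 and 1495 UMIs. The log2 ratio was -1.60 [-1.69, -1.52], a 3.04-fold difference. Barrier endothelial subclusters held 876 and 381 CPM (log2 ratio -1.20 [-1.31, -1.10]), and the other endothelial subclusters 179 and 75.3 CPM (-1.25). Pericyte-like cells held 620 and 531 CPM (-0.22 [-0.37, -0.07]). Lymphatic endothelial-like cells held 12.4 and 5.74 CPM (-1.11 [-2.06, -0.24]), macrophage-like cells 11.7 and 7.86 CPM (-0.58 [-1.03, -0.13]) and fibroblast-like cells 9.73 and 10.95 CPM (0.17 [-0.22, 0.56]). Among endothelial subclusters the log2 ratio ran from -1.33 in the main barrier subcluster to -0.14 [-0.36, 0.08] in an arterial subcluster with barrier genes. That arterial subcluster held 1281 and 1165 CPM, in only 96 and 28 cells. With every subcluster given the same weight in both libraries, the ratio for the class was -0.90 [-0.99, -0.81].

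After thinning, 38.1% of endothelial-like cells in the Foxq1flox/flox library and 18.3% in the Foxq1iECKO library had a Foxq1 UMI. This left out 262 and 204 shallow cells, and the unthinned shares were 49.98% and 27.5%. In barrier subclusters the thinned shares were 75.2% and 41.8% (92 and 66 cells left out; 88.5% and 57.0% unthinned). In pericyte-like cells they were 51.8% and 50.6% (36 and 43 left out; 58.7% and 62.1% unthinned), shares from which no order was read. Neuron-like cells, which gave the background from free RNA, had 1.68% and 1.58% (212 and 140 left out; 3.28% and 1.81% unthinned). The median UMI count was 4836 and 4594 in endothelial-like, 5552 and 4086 in barrier, 3754 and 3720 in pericyte-like, and 3077 and 2891 in neuron-like cells.

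In the mouse build mm10 (GENCODE annotation), Foxq1 lies on the plus strand of chromosome 13 from 31556134 to 31560976, with 1 transcript of 1 exon. The coding sequence runs from 31558917 to 31560116, between untranslated regions from 31556134 to 31558916 and from 31560117 to 31560976. The labels do not give the position of the deleted part and the counts are 3′ tags, so a UMI in the Foxq1iECKO library need not come from a transcript with an intact coding sequence.

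**Figure D1:**
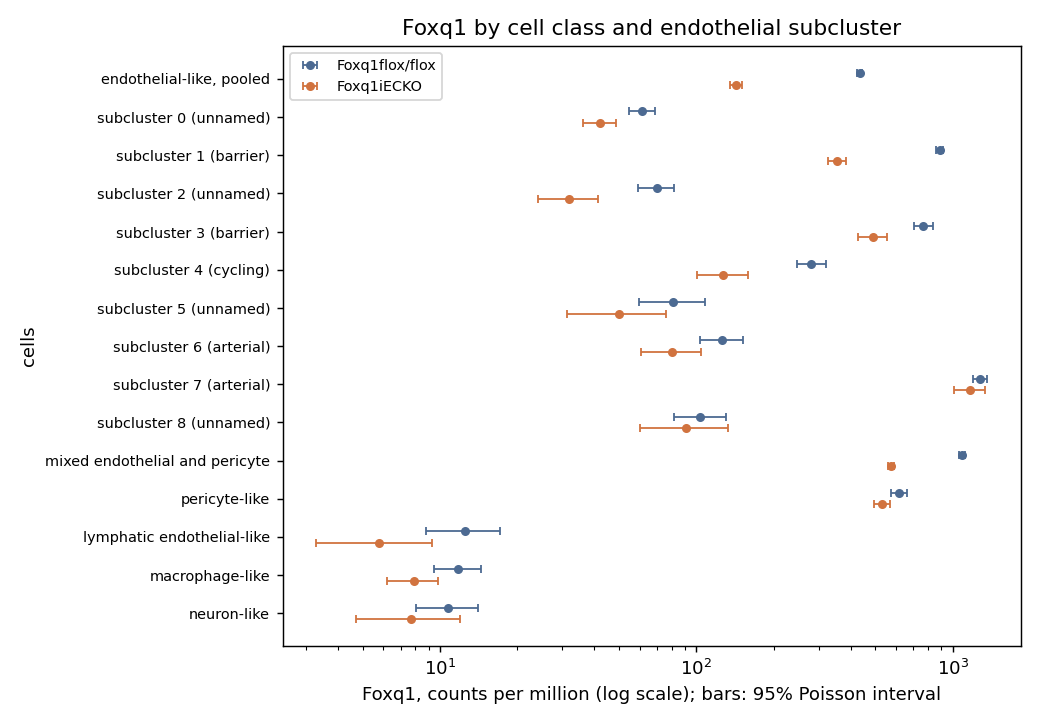
Foxq1 level in CPM on a log axis, by cell class and endothelial subcluster, for both libraries, with bars for the 95% Poisson interval. The endothelial-like values are 434 and 143 CPM and the pericyte-like values 620 and 531 CPM.

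Endothelial-like cells made up a smaller share of the Foxq1iECKO library, and macrophage-like cells and a cluster with endothelial and pericyte genes a larger share. Endothelial-like cells were 17.2% [16.6, 17.9] and 12.3% [11.7, 12.8] of the cells used. The mixed endothelial and pericyte cluster, led by Rgs5, Abcc9, Foxq1, Foxf2 and Spock2, was 3.92% [3.60, 4.26] and 7.14% [6.69, 7.60]. Macrophage-like cells were 11.03% and 16.0%, and neuron-like cells 11.4% and 6.16%. Neural crest-like cells were 0.217% and 0.613%, from 29 and 77 cells. Of the other classes, fibroblast-like cells were at 16.9% and 17.8%, radial glia-like cells at 7.15% and 8.38%, leukocyte-like cells at 5.93% and 5.14%, and pericyte-like cells at 2.10% and 2.501%. Lymphatic endothelial-like cells were 2.13% and 2.01%, and unnamed clusters, among them cartilage clusters kept out of the fibroblast class, 15.8% and 15.1%. The endothelial-like class joined a cluster led by Cyp1a1 and Gbp2 (890 and 747 cells), a cluster of low UMI count led by Zfp366 and Tek (836 and 580) and a barrier cluster led by Spock2 and Synm (579 and 212).

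Cells had passed a CD31 bead sort, so these shares describe what the sort retained and not the makeup of the brain. Clusters led by cartilage genes (965 and 562, and 315 and 294 cells) and skeletal muscle-like cells (69 and 69) were also present. The libraries thus held some tissue from outside the brain, and endothelial-like cells may include vessels from there. What part these were in each library was not measured, and it could move the barrier share and pooled ratios. When 1840 genes that were 1.5-fold apart between the libraries in any class were left out of the variable genes, endothelial-like cells were 18.8% and 14.6%, the mixed cluster 2.87% and 5.51%, macrophage-like cells 11.03% and 16.0% and neuron-like cells 11.1% and 5.97%. Counting the mixed cluster as endothelial gave 21.1% and 19.4%.

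**Figure D2:**
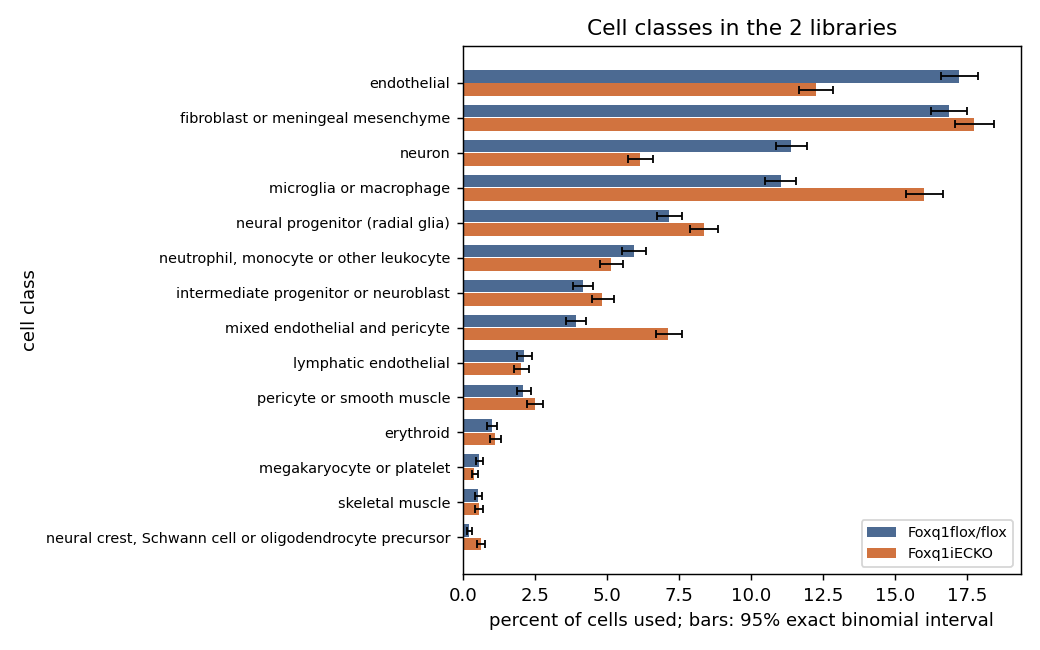
Share of the cells used, in percent, by named cell class in both libraries, with bars for the 95% exact binomial interval; unnamed clusters are not drawn. Endothelial-like cells are 17.2% and 12.3% and the mixed endothelial and pericyte cluster is 3.92% and 7.14%.

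Within the endothelial-like cells, subclusters with blood-brain barrier markers were a smaller part in the Foxq1iECKO library. They were 35.0% [33.0, 37.0] and 24.95% [22.8, 27.2] of endothelial-like cells. The main barrier subcluster, led by Apod, Synm, the pericyte gene Rgs5 and Foxf2, was 24.2% and 13.8%. An arterial subcluster with barrier genes, led by Fbln2, Cxcl12 and Mal, was 4.16% and 1.82%, and the other arterial subcluster, led by Gja5, was 6.12% and 6.95%. An unnamed subcluster led by the immune genes Gbp2, Ccl2, Cxcl10 and Rsad2 was 18.9% and 25.5%, and one led by the immediate early genes Egr1 and Fos was 13.7% and 17.3%. The cycling subcluster was 10.4% and 10.8%. Without the 88 genes that were 1.5-fold apart in endothelial-like cells, Foxq1 among them, the barrier share was 38.4% and 26.4%. Counting the mixed cluster with the barrier subclusters turned the direction, to 47.0% and 52.6%.

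Of 6184 genes at 20 or more CPM in pooled endothelial-like cells, 34 were higher and 54 lower by size in the Foxq1iECKO library. The balance turned with the choice and weighting of cells, to 53 higher and 8 lower with a marker gate per cell, 91 and 13 with the mixed cluster added, and 21 and 12 with subclusters weighted equally. After Foxq1, lower genes were Ddc, the aromatic amino acid decarboxylase (21.8 and 8.11 CPM, log2 ratio -1.43 [-1.78, -1.08]), Slc25a33, a mitochondrial nucleotide carrier (31.8 and 12.9 CPM, -1.30), and the heat shock gene Hspa1a (65.2 and 30.2 CPM, -1.11). The lipocalin gene Apod held 98.5 and 47.2 CPM (-1.06), and Mfsd2a, a lipid transporter of brain endothelium, 42.5 and 21.5 CPM (-0.99 [-1.21, -0.77]). Mal (-0.9955), Gja4, a gap junction gene (-0.996), Synm (-0.87), Htra3 (-0.85) and Apcdd1, an inhibitor of Wnt signalling (451 and 266 CPM, -0.76 [-0.82, -0.70]), were also lower. Within barrier subclusters the lower ratios of Mfsd2a (-0.17), Mal (-0.21), Htra3 (-0.05) and Apcdd1 (-0.04) were nearer to 0, while those of Foxq1 (-1.20), Slc25a33 (-1.27), Ddc (-1.05), Hspa1a (-0.95) and Gja4 (-0.69) were beyond the size limit. With the mixed cluster added, Foxq1 was at -0.81, Slc25a33 at -0.51, Ddc at -0.31, Hspa1a at -0.10 and Gja4 at -0.54, so that of these 5 Foxq1 alone was beyond it. With equal weights, Slc25a33 (-0.57) and Gja4 (-0.47) were inside it. Apod, Synm and Htra3 also led the main barrier subcluster, whose share was smaller in this library. Hspa1a shares reads with its near-identical copy Hspa1b and is uncertain for that reason.

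The highest genes held several interferon-induced genes. Oasl2 was at 13.8 and 28.8 CPM (log2 ratio 1.06 [0.81, 1.31]), Igtp at 21.8 and 43.9 CPM (1.01), Iigp1 at 27.03 and 52.1 CPM (0.95), Gbp3 at 24.8 and 45.8 CPM (0.88), Gbp2 at 83.5 and 148 CPM (0.83) and Ifitm3 at 184 and 295 CPM (0.68). Thbs1, which encodes the angiogenesis inhibitor thrombospondin, was at 65.6 and 125 CPM (0.93 [0.81, 1.05]). Cyp1a1, a target of the aryl hydrocarbon receptor, was at 366 and 653 CPM (0.84 [0.79, 0.89]). Slc7a11, the cystine transporter (1.06), the fatty acid binding protein gene Fabp4 (0.91), Rnf213 (0.85) and Cmss1 (0.77) completed the higher genes. Cyp1a1 was also higher in lymphatic endothelial-like (0.74), fibroblast-like (0.87) and macrophage-like cells (0.93) and was lower in pericyte-like cells (-0.43). Cmss1 was higher in all 4 of these classes (0.93, 0.76, 0.77 and 0.51). Within barrier subclusters Slc7a11 was at 0.00 and Iigp1 at -0.40. With subclusters weighted equally, Thbs1 (0.57), Cyp1a1 (0.58), Gbp2 (0.44), Iigp1 (0.48), Ifitm3 (0.52) and Fabp4 (0.40) were inside the size limit. Oasl2 (1.07), Slc7a11 (0.82), Igtp (0.81), Cmss1 (0.76), Rnf213 (0.71) and Gbp3 (0.65) stayed beyond it. Gbp2, Cyp1a1 and Thbs1 also led an unnamed subcluster whose share was larger in the Foxq1iECKO library.

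Genes of the blood-brain barrier were lower as a group in pooled endothelial-like cells of the Foxq1iECKO library. Of 34 transporter and metabolic genes listed, 29 were measured, 0 were higher and 10 lower by size, with a median log2 ratio of -0.48 [-0.53, -0.42], below all 10000 random lists. Among those lower by size were Spock2 (583 and 349 CPM, -0.74) and the transferrin receptor gene Tfrc (736 and 477 CPM, -0.62). Slc2a1, the glucose transporter (515 and 366 CPM, -0.49), was inside the size limit. The median was -0.04 with subclusters weighted equally and 0.03 within barrier subclusters, where 31 genes were measured, 0 were higher and 0 lower by size, and Spock2 was at 1162 CPM in both libraries. These subclusters were formed and named by barrier genes, so a cell with lower barrier genes would fall outside them. Values within them, or with subclusters weighted equally, therefore do not separate fewer barrier cells from lower barrier expression per cell. With the mixed cluster added, the median was -0.12. That cluster was 39.4% and 70.0% of the barrier and mixed cells, so the pooled median also depends on where its cells are placed. Within barrier subclusters Slc2a1 was at 873 and 798 CPM (-0.13 [-0.21, -0.05]) and Mfsd2a at 90.8 and 81.0 CPM. Tight and adherens junction genes (23 of 25 measured) had a median of -0.15, with 0 higher and 3 lower, Cdh2 (-0.59), Marveld2 (-0.78) and Lsr (-0.63); it was -0.02 with equal weights and -0.01 in barrier subclusters. Claudin-5 (Cldn5) was at 63.4 and 53.2 CPM (-0.25) in the pooled class and at 93.9 and 103 CPM in barrier subclusters.

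Wnt receptors and targets (26 of 30 measured) had a median of -0.12, with 1 higher, Myc (44.2 and 69.1 CPM, 0.64), and 4 lower, among them Apcdd1 and Nkd1 (47.4 and 27.8 CPM, -0.77). That median was -0.02 with equal weights, and Lef1 (-0.46 pooled) was at -0.16 in barrier subclusters. Fenestration and vesicle genes (17 of 18 measured) had a median of 0.16, above all random lists, with 1 higher, Fabp4, and 0 lower; Cav1 was at 479 and 588 CPM (0.30) and Plvap at 98.5 and 114 CPM (0.21). Within barrier subclusters this list had a median of -0.11 and Plvap a log2 ratio of -0.15.

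Lists for vessel growth and for arterial and venous genes were measured in the pooled class. Tip cell and sprouting genes (26 of 28 measured) had a median of -0.03, at percentile 22.2, with 0 higher and 1 lower, the Notch ligand Dll4 (71.4 and 43.7 CPM, -0.71). VEGF receptor and angiopoietin genes (25 of 28) had a median of -0.11, at percentile 0.27, with 0 higher and 2 lower, Nr4a1 (-0.65) and Spry4 (-0.59). The receptor genes Kdr (2392 and 2122 CPM, -0.17) and Flt1 (1403 and 1192 CPM, -0.23) were inside the size limit. Within barrier subclusters the tip cell median was 0.05 and the VEGF median -0.01; with equal weights they were -0.05 and -0.08, and with the mixed cluster added -0.11 and -0.17. Notch signalling genes (16 of 20) had a median of -0.14 (percentile 0.74), with Dll1 higher (6.07 and 10.0 CPM, 0.72) and Dll4 lower, and Hey1 at 374 and 271 CPM (-0.46). The Notch median was -0.06 with equal weights (percentile 13.9) and -0.05 in barrier subclusters (18.65). Arterial genes (16 of 24) had a median of -0.25, below all random lists, with 0 higher and 2 lower, and venous genes (14 of 18) 0.15 (percentile 99.97), with Selp higher (0.72) and Slc38a5 lower (-0.69). The arterial median was -0.15 with equal weights (percentile 0.07) and -0.08 in barrier subclusters (10.15). The venous median was 0.03 with equal weights (percentile 84.7), 0.16 in barrier subclusters (99.3) and -0.05 with the mixed cluster added. Basement membrane genes (24 of 27) had a median of -0.04 (percentile 9.80) with 0 higher and 0 lower, and Col4a1 at 2423 and 2392 CPM. The median was -0.04 for BMP and TGF-beta genes (21 of 25; 1 higher, Ccn2 at 0.59, and 0 lower) and 0.06 for forkhead genes (17 of 22; 0 higher and 1 lower, Foxq1).

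Interferon response genes were higher in endothelial-like cells of the Foxq1iECKO library. Of 30 listed, 21 were measured, 10 were higher and 0 lower by size, with a median of 0.52 [0.41, 0.64], above all random lists. Among those higher by size were Ifit3b (4.70 and 12.4 CPM, 1.40) and Rsad2 (36.1 and 77.1 CPM, 1.09). B2m (655 and 785 CPM, 0.26) was inside the size limit. The median was 0.41 with equal weights and 0.60 within barrier subclusters. The median was also above 0 in lymphatic endothelial-like (0.27), pericyte-like (0.42), fibroblast-like (0.45), neuron-like (0.47) and macrophage-like cells (0.49) and in the mixed cluster (0.53). In neuron-like cells only 6 of the 30 genes were measured. An interferon-high macrophage cluster led by Rsad2 and Ifit1 held 87 and 246 cells.

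Of the remaining lists, the medians were 0.06 for S phase genes (38 of 41 measured; 0 higher and 0 lower; percentile 99.7), 0.06 for G2/M genes (49 of 52; 0 and 0; 99.7), 0.04 for hypoxia and glycolysis genes (23 of 31; 0 and 0; 90.5), and 0.05 for unfolded protein and integrated stress genes (18 of 22; 2 higher and 0 lower; 91.65). They were -0.05 for p53 targets (21 of 25; 0 higher and 1 lower, Pmaip1 at -0.63; 21.4), -0.02 for leukocyte adhesion genes (16 of 20; 2 higher, Selp and Ccl2 at 0.91, and 0 lower; 49.2) and -0.10 for mesenchymal transition genes (15 of 23; 0 higher and 1 lower; 3.51). Immediate early genes (24 of 24) had a median of -0.07 (percentile 1.78), with 0 higher and 3 lower, Hspa1a, Hspa1b (-0.67) and Nr4a1 (-0.65). That median turned to 0.026 with equal weights, 0.039 with the mixed cluster added and 0.00089 with the marker gate. The G2/M median turned to -0.0069 with equal weights and the S phase median to -0.018 with the marker gate. Mitochondrially encoded genes (13 of 13) had a median of 0.01, with 0 higher and 0 lower.

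Transcripts of other cell types were also measured in the endothelial-like cells. Haemoglobin genes (6 of 7 measured) had a median of -0.25, with 0 higher and 1 lower, Hbb-y (188 and 123 CPM, -0.61), and -0.97 within barrier subclusters, where 5 were lower. Their median turned to 0.10 with equal weights and 0.056 with the marker gate. Medians were 0.28 for pericyte genes (3 of 14 measured), 0.27 for macrophage genes (5 of 16), 0.06 for neuronal genes (6 of 15) and -0.10 for neural progenitor genes (7 of 15), each with 0 higher and 0 lower, and -0.14 for fibroblast genes (6 of 13; 0 higher and 1 lower, Pdgfra at -0.71). The percentiles among random lists were 0.06 for haemoglobin, 99.6 for pericyte, 97.85 for macrophage, 82.8 for neuronal, 10.7 for neural progenitor and 8.05 for fibroblast genes. Within barrier subclusters the median log2 ratios were 0.38 for pericyte (percentile 98.6), 0.70 for macrophage (99.6) and 0.54 for fibroblast genes (99.99). Sex-linked genes (5 of 6) had a median of 0.35, with 0 higher and 0 lower by size; the female transcript Xist was at 355 and 248 CPM (-0.52) and the Y-linked Ddx3y at 93.0 and 119 CPM (0.35). Within barrier subclusters Xist was at -0.03 and Ddx3y at -0.37, and the list median was -0.037. Xist and Y-linked transcripts were present in both libraries. The list joins Xist with Y-linked genes, so its median is not read as a shift. Over all cells used, Xist was lower and Ddx3y higher in the Foxq1iECKO library. The mix of sexes may therefore differ between the libraries, which cannot be told apart from genotype with 1 library each.

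**Figure D3:**
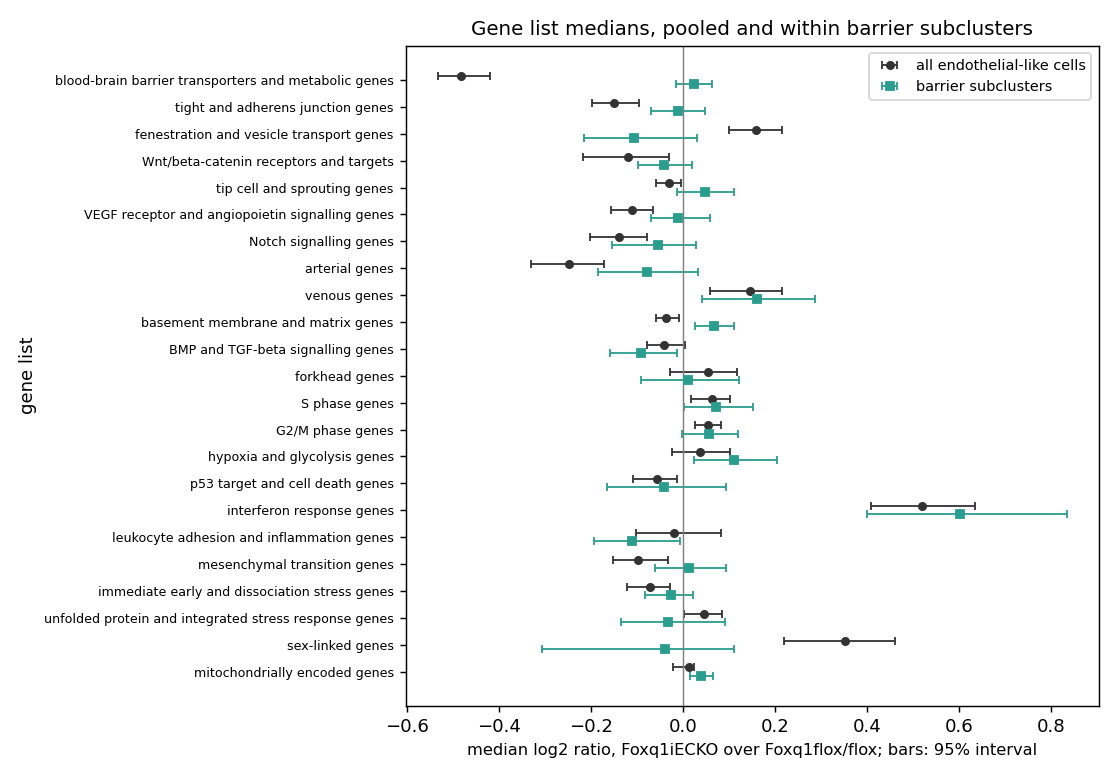
Median log2 ratio of gene lists (Foxq1iECKO over Foxq1flox/flox) in pooled endothelial-like cells and within barrier subclusters, with bars for the 95% interval from Poisson draws; lists of carry-over genes are not drawn. The blood-brain barrier list lies at -0.48 pooled and 0.03 within barrier subclusters, and the interferon list at 0.52 and 0.60.

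Barrier subclusters, compared after the pooled values had been seen, held higher interferon genes. Of 6273 genes, 111 were higher and 60 lower by size. Higher were the basement membrane collagen gene Col15a1 (387 and 881 CPM, 1.19, against 0.49 in the pooled class and 0.28 with equal weights), the only one of 24 measured basement membrane genes higher by size (list median 0.07), the chemokine gene Cxcl12 (128 and 297 CPM, 1.21), Cyp1b1 (1.08), Oasl2 (2.11), Gbp3 (1.60), Igtp (1.38), Parp12 (1.34) and Irgm1 (1.22). Lower, after Foxq1, were Slc25a33 (-1.27), Klhl28 (-1.14), Ddc (-1.05), Cd59a, an inhibitor of complement (-0.94), and Hey1, a Notch target (531 and 340 CPM, -0.64). Fibroblast (0.54) and pericyte (0.38) list medians were also above 0 in these subclusters, which held 806 and 384 cells. Their mix differed, with 558 and 213 cells in the main subcluster and 248 and 171 in one of low UMI count. Cxcl12 was among the genes that led the latter, so its ratio also moves with that mix. In the whole class the Cxcl12 ratio was 0.22 [0.11, 0.32] pooled and 0.68 with subclusters weighted equally.

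The mixed cluster showed lower Foxq1 (1085 and 575 CPM, -0.91 [-0.97, -0.86]) and higher Col15a1 (162 and 428 CPM, 1.40), Cyp1a1 (28.5 and 112 CPM, 1.98) and Hmox1, the haem oxygenase gene (93.3 and 182 CPM, 0.97). Rel (-0.80), Cdc42ep3 (-0.67) and Prdm1 (-0.60) were lower there. Its cells had a median of 8765.5 and 8514.5 UMIs (doublet score medians 0.0594 and 0.0538, against 0.0325 and 0.0345 in endothelial-like cells).

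The share of endothelial-like cells with a UMI of the proliferation genes Mki67 or Top2a was alike in both libraries. After thinning it was 55.1% [52.9, 57.3] and 55.6% [52.9, 58.3], a log2 ratio of 0.01 [-0.12, 0.15], with 262 and 204 cells left out; unthinned shares were 66.9% and 67.4%. Barrier subclusters had 42.7% and 46.2%. Neuron-like cells, at median depths of 3077 and 2891 UMIs, had 12.3% and 16.4% (17.0% and 21.7% unthinned). Their G2/M list median was 0.49, with 12 of 40 measured genes higher, so these shares are not read as background from free RNA. Per thinned cell, the mean number of S phase UMIs was 6.13 (SD 5.13) and 6.60 (SD 5.41), and of G2/M UMIs 13.7 (SD 13.7) and 13.9 (SD 13.4).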

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

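The alternatives that added the mixed cluster, counted it with the barrier subclusters, left out the endothelial-like cluster of low UMI count, kept only barrier subclusters or clustered without genes 1.5-fold apart were chosen after the results had been seen. No paired analysis was possible because each genotype had 1 library. Foxq1 stayed lower in endothelial-like cells of the Foxq1iECKO library in every alternative run. Its log2 ratio, -1.60 as reported, was -1.69 with the stricter cell filter, -1.79 without the low-UMI cluster, -1.21 with cells weighted equally, -1.20 in barrier subclusters, -1.08 with the marker gate, -0.90 with subclusters weighted equally and -0.81 with the mixed cluster added; the cause was not tested.

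Of 88 genes 1.5-fold apart (34 higher, 54 lower), the count became 33 (21 and 12) with subclusters weighted equally, 48 (18 and 30) and 293 (127 and 166) at minimums of 50 and 5 CPM, 138 (45 and 93) without the low-UMI cluster and 171 (111 and 60) in barrier subclusters. It was 61 (53 and 8) with the marker gate and 104 (91 and 13) with the mixed cluster added. Median-of-ratios and TMM scaling both gave 85 (37 and 48). At the other minimums the cause is the number of genes compared; elsewhere the cause was not tested. Of the 24 named genes, the rule named 15 again with the marker gate, 13 with equal subcluster weights, 14 at a minimum of 50 CPM, 8 with the mixed cluster and 10 in barrier subclusters, where Iigp1 turned to -0.40.

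The barrier list median, -0.48 as reported, was -0.74 without the low-UMI cluster, -0.55 with the stricter filter, -0.27 with cells weighted equally, -0.22 with the marker gate, -0.12 with the mixed cluster, -0.036 with equal subcluster weights and 0.025 in barrier subclusters. The subclusters were formed on these genes among others, so equal weights or barrier subclusters alone do not separate fewer barrier cells from lower expression per cell. The junction list (-0.15) was -0.082 with cells weighted equally, -0.064 with the gate, -0.016 with equal subcluster weights and -0.010 in barrier subclusters. The fenestration list (0.16) was 0.066 and 0.078 with equal cell and subcluster weights, -0.038 with the mixed cluster and -0.11 in barrier subclusters. The Wnt list (-0.12) was -0.016 with equal subcluster weights and 0.027 at 50 CPM. The tip cell list (-0.03) was -0.0037 with the stricter filter, 0.022 with the gate, -0.11 with the mixed cluster and 0.048 in barrier subclusters.

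Signs also turned for S phase genes (-0.018), immediate early genes (0.00089) and haemoglobin genes (0.056) with the gate, for G2/M (-0.0069), immediate early (0.026) and haemoglobin genes (0.10) with equal subcluster weights, for venous (-0.045) and immediate early genes (0.039) with the mixed cluster, and for sex-linked genes at 50 CPM (-0.081) and in barrier subclusters (-0.037). The number of lists among the outer 2.5% of random lists on either side, 16 as reported, was 10 with the gate, 8 with equal subcluster weights and 8 in barrier subclusters. The cause of these shifts was not tested.

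The log2 ratio of the endothelial-like share, -0.49 as reported, was -0.28 at resolution 0.5, -0.36 without genes 1.5-fold apart, -0.66 with each library clustered on its own and -0.13 with the mixed cluster. The arterial share within the class (-0.23 [-0.54, 0.08]) was 0.18 at resolution 0.3, 0.13 without cycle genes, 0.20 with doublets kept and 0.21 without genes 1.5-fold apart. The barrier share (-0.49) was 0.16 with the mixed cluster counted. The cause was not tested. Among alternative values of the results named in the design, 106 stayed within their counting interval or within 1.5 times their count, 45 moved and 5 turned sign. Among those of single named genes and other lists, 507 stayed, 153 moved and 11 turned sign. Depth limited small groups: in an endothelial subcluster with 47 and 22 Foxq1 UMIs the interval of the log2 ratio ran from -1.50 to 0.06.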

Other observations

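The test of attached cells and the test of macrophage RNA were set before their results were seen. The Foxq1 ratio with equal subcluster weights was an alternative fixed before the data were examined. Its use as a test of a cause was chosen after, as were all other tests given here. Genes at the extremes of other classes are given as values, since no list was fixed for them. In intermediate progenitor-like cells 103 genes were higher and 297 lower by size in the Foxq1iECKO library. That class joined a cluster led by Neurod6, Eomes and Tbr1 (445 and 553 cells) and one led by the ventral forebrain genes Dlx1, Sp9 and Dlx2 (113 and 55 cells), so its ratios move with that mix. Radial glia-like cells held more Eomes, a gene of cortical intermediate progenitors (12.9 and 61.7 CPM, log2 ratio 2.26), and Neurod1 (2.29), and less Penk (-3.31). Neuron-like cells held more Cyp26b1, which breaks down retinoic acid (2.74), Fabp7 (2.24) and Trp73 (2.02). The G2/M list median went both ways among classes, at 0.49 in neuron-like (12 of 40 measured genes higher) and 0.35 in pericyte-like cells, and at -0.25 in lymphatic endothelial-like and -0.26 in fibroblast-like cells. It was -0.01 in macrophage-like cells and 0.04 in the mixed cluster. In fibroblast-like cells Ibsp, the bone sialoprotein gene, was at 109 and 3.50 CPM (-4.96), while the fibroblast-like cluster led by Ibsp held 546 and 711 cells.

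In macrophage-like cells the collagen genes at the extremes went both ways, with Col1a1 at 46.3 and 175 CPM (1.91), Col1a2 at 1.47, Col3a1 at 1.54, Col2a1 at -1.60 and Col9a1 at -0.93; the macrophage-like cluster led by Lyve1 and F13a1 held 663 and 1012 cells and the one led by P2ry12 726 and 755. The endothelial Cdh5 (32.4 and 17.2 CPM, -0.91) was lower there. Cdh5, the endothelial cadherin gene, was looked at first as a pattern to weigh and is given as values. Its log2 ratio was -0.21 [-0.24, -0.17] in endothelial-like cells, -0.30 [-0.34, -0.26] with equal subcluster weights, -0.37 in barrier subclusters and -0.30 [-0.41, -0.20] in lymphatic endothelial-like cells, and the median of the other endothelial markers with equal subcluster weights was -0.12. In lymphatic endothelial-like cells Il33 (-1.52) and Cd34 (-0.81) were lower and Casz1 (1.74) was higher. Over all cells used, Xist was at 588 and 376 CPM (-0.65) and Ddx3y at 88.2 and 124 CPM (0.49), with Xist ratios by class from -1.90 in unnamed clusters to -0.03 in intermediate progenitor-like cells.

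Foxq1 was lower in endothelial-like cells of the Foxq1iECKO library. A smaller share of cells in barrier subclusters, which held most Foxq1 of the class, may account for part but not for all. The log2 ratio was -0.90 [-0.99, -0.81] with each subcluster given the same weight in both libraries. Foxq1 is itself among the markers that name these subclusters, so the size of that part was not separated. Counting the mixed cluster with them turned the direction of the share, while Foxq1 was at -0.81 with that cluster added to the class. Poorer capture of Foxq1 in the whole library is argued against by pericyte-like cells, where the ratio was -0.22 [-0.37, -0.07]; it was -0.58 [-1.03, -0.13] in macrophage-like and 0.17 in fibroblast-like cells, near the background level. Loss in endothelial cells of this genotype is a candidate explanation: the pooled endothelial ratio lay below the pericyte ratio by -1.38. That gap also includes the smaller share of cells placed in barrier subclusters. The ratio of -0.90 with the same subcluster weights in both libraries also lay below -0.22. In the arterial subcluster with barrier genes, the counting interval did not exclude an equal level. With 96 and 28 cells, that value is not read as spared Foxq1 in a subtype. Loss in endothelial cells stays a hypothesis, since 3′ tags do not show whether the coding sequence was deleted.

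The mixed endothelial and pericyte cluster was larger in the Foxq1iECKO library, at 39.4% and 70.0% of the barrier and mixed cells. Chance pairs do not account for it, since the Foxq1iECKO library held 145.5 times the number expected at a doublet share of 8%. Pairs left attached in dissociation may do so: 99.7% of 1072 genes 2-fold apart between barrier and pericyte-like cells lay between them, with 25% tolerance, at a best mix of 67.1% barrier and 32.9% pericyte RNA. The cluster was called mixed because it held markers of both, so this share is a weak test. Foxq1 in the mixed cluster (1085 and 575 CPM) lay above its level in barrier subclusters (876 and 381 CPM) and in pericyte-like cells. Single cells with both programmes would give the same profile and stay open, and so does whether attachment or genotype differed between the libraries. Depth does not decide, as the mixed medians of 8765.5 and 8514.5 UMIs lay near the sum for all barrier and pericyte-like cells (9306 and 7806) and below that for the main barrier subcluster (12345.5 and 10907), a second comparison made after the first.

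Interferon response genes were higher in the endothelial-like cells of the Foxq1iECKO library. A response of endothelial cells alone is argued against by classes without an endothelial programme, since the smallest median log2 ratio among the 4 looked at was 0.42, in pericyte-like cells, and all 4 lay at percentile 99.85 or above among random lists. The neuron-like value rests on 6 measured genes. Carry-over of RNA into these 4 classes was not tested, so they are not 4 independent arguments. RNA carried over from interferon-high macrophages is argued against too, since 24.4% of endothelial RNA would have to come from macrophages, and 10 macrophage genes allowed at most 0.255%. A difference between the brain collections that goes with the genotype label and an effect of the genotype on the whole embryo cannot be told apart with 1 library each. Both could give the median of 0.46 over these 4 classes.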
